A study of Arabidopsis thaliana with 4 samples.

How the data were processed

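Endosperm RNA from 3 laser-captured samples and 1 reference RNA from the remaining silique tissue were compared on 4 two-channel arrays. Per the labels' protocols, RNA was isolated with a kit for small samples, amplified in 2 rounds of in vitro transcription, labelled through amino-allyl nucleotides coupled to Cy dyes and fragmented before hybridisation. Amplification starts at the 3' end of transcripts and can change the proportions between transcripts, and both channels went through it. Only the authors' table of log ratios was used, with 1 value per probe and array. The deposited values are taken as log2 ratios of the channels: they have both signs, a mean within 0.003 of 0 on each array and a range from -6.12 to 4.82. Scanner, background correction, normalization, the filter that left cells empty, the log base and the numerator are not given in the sources used here. If the log base were another, folds would differ, as would counts past a fold and the test against a fold change of 1.5, while p-values against no change would not. All pairs of arrays correlated above 0, so both dye orientations already ran one way. Which RNA is the numerator was set from the endosperm marker list by a rule fixed before the data were examined: its median was above 0 on each array (1.67, 1.89, 1.82 and 1.31), so endosperm is the likely numerator.

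The platform's gene table names 14539 of the 26912 probes, each with 1 gene, 0 with several, and leaves 12373 unnamed here. Of the named probes, 14485 were matched through their gene identifiers to the RefSeq gene table of assembly TAIR10.1, which was used for names and for which genes neighbour each other. No coordinates are printed, since the array's build is not given in the sources used here. Of the probes with values on all 4 arrays, 10675 were named, for 10513 genes. Many genes with a well-known symbol have no named probe, so the gene lists are thin. Probes of 1 gene were averaged per array for the lists. Across the 117 genes with 2 or 3 probes, the first 2 probes correlated with r = 0.625. There were 3 genes with 17 probes each.

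The 2 arrays of replicate 2 hold the same 2 RNAs and were averaged first, so n = 3 throughout. The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided, Benjamini-Hochberg, adjusted p under 0.05). A dye effect cancels in this mean, since 1 replicate carries each dye and replicate 2 both. Errors are SDs over the 3 replicates. Without intensities no filter on dim spots was possible, and the number of arrays limits the precision. Lists of genes fixed before the data were examined were endosperm, embryo, seed coat and silique wall and vascular markers, photosynthesis, cell cycle, CDK inhibitors, DNA replication, core histones, chromatin and DNA methylation, small RNA pathways, spindle and cytokinesis, tubulins, cytokinin, seed storage and oil body, and heat shock. Cytosolic ribosomal proteins were to be found by gene description, which the table lacks, so their loci were listed from general knowledge after the data were examined and after the value of AT5G09490 had been seen. Lists with at least 3 measured genes (10 lists) were compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation, with which no list passed. In that second form camera uses the 2 residual degrees of freedom of 3 samples, so few lists could pass.

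Named genes follow a rule fixed before the data were examined. It takes the 10 highest and 10 lowest mean ratios among named probes that passed with 1 sign on all 4 arrays. From each list it takes up to 4 members with the smallest p among those that passed, or the 2 with the largest ratio in size where none did. MEA, FIS2, PHE1, AGL62 and FWA are named where measured, which holds for PHE1 and AGL62. IKU1, BAN, DFR, AUR2 and the tubulins that did not pass were named after their values were seen, to complete counts of 5 or fewer, as was HTR5, the 1 core histone gene called lower.

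The test was tried on simulated data of 19449 probes with 200 changed, in 20 draws. With variances drawn from the fitted prior, it recovered 0.7% of changes of 0.58 (log2), 24.6% of changes of 1 and 92.2% of changes of 2, and 5.2% of its calls were false. With the variances fitted to each probe it recovered 18.7%, 91.9% and 99.8% of the same changes, and 11.2% of calls were false, above the nominal level. In the data far more probes were called (57.5%) than the 200 changed here. The adjusted threshold was therefore stricter in the simulation, and its rates do not describe the comparison of the data itself. In list tests, camera called a list of 20 genes shifted by 1 in 9 of 20 draws and by 2 in 20 of 20 draws, and it called 0 and 2 of 1000 unshifted lists. The genes were simulated without correlation between them, and the draws picked lists from 1 simulated data set. These list rates therefore do not cover lists of correlated genes. An earlier version with a single draw missed the list shifted by 1, after which the shift of 2 was added. Alternatives were the dye as a covariate, other uses of the arrays of replicate 2, other scalings, filters on probes, robust variances, a fold threshold, gene-level means and each replicate left out.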

Results

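Transcript levels in the endosperm, the nutritive tissue that surrounds the embryo in the seed, were measured in Arabidopsis thaliana at 4 days after pollination on 2-colour arrays of spotted oligonucleotides. Endosperm was cut from silique sections with a laser, and 3 such samples were each hybridised against 1 common reference RNA, the silique tissue that was left on a slide after the cutting. Replicate 1 carried Cy3, replicate 3 carried Cy5, and replicate 2 was hybridised on 2 arrays with the dyes swapped, which gave 4 arrays. The arrays held values for 21829 probes (replicate 1), 22035 and 23171 probes (replicate 2 with Cy3 and with Cy5) and 22902 probes (replicate 3). Their median log2 ratios, in the same order, were 0.12, 0.09, 0.05 and 0.05. Of the 26912 probes, 19449 had a value on all 4 arrays and were compared. Across these probes, which are not independent replicates, Pearson's r between arrays lay between 0.87 (replicate 1 against replicate 2 with Cy5) and 0.92 (replicate 1 against replicate 2 with Cy3). The 2 arrays of replicate 2 gave r = 0.92, and their values differed with an SD of 0.42 on the log2 scale. Ratios are given as endosperm over reference, which is the likely direction: the sources used here do not state the numerator, and it was set by a list of endosperm marker genes. The log base is taken as 2 and is not stated either.

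The first question was which transcripts differ between proliferating endosperm and the rest of the silique. Transcripts of 10 of 11 measured endosperm markers, of all 4 measured genes of DNA replication and of 2 phragmoplast kinesins were higher in endosperm. The lists of replication and of spindle and cytokinesis, with 4 and 3 measured genes, did not pass against other genes (camera adjusted p = 0.142 for each). Lists this small have little power in that test. In contrast, transcripts of a sucrose transporter, an auxin-conjugating enzyme and a beta-tubulin were among those far below the reference. Of the 19449 probes, 6231 were higher and 4957 lower in endosperm (limma, Benjamini-Hochberg adjusted p under 0.05, 2 residual degrees of freedom per probe), or 57.5% in all. With each array centred on its median the excess ran the other way, with 5415 higher and 5552 lower. All 4 arrays had 1 sign for 11017 of the 11188 called probes, and for 13942 of all 19449. The calls rest on these same arrays, so their shared sign is no separate evidence. The extremes were uneven: 1039 probes lay over 4-fold below the reference and 341 lay over 4-fold above it, whereas past 2-fold the numbers were 2692 lower and 2517 higher. If the reference were the numerator, 341 probes would lie over 4-fold below it and 1039 above, and higher and lower, with the highest and lowest genes named next, would trade places throughout. The median log2 ratio over all probes was 0.11, and the median SD between the 3 replicates was 0.23. Against a fold change of 1.5 in place of no change, 4885 probes passed (2364 higher and 2521 lower). At the level of genes, tested against no change, 3571 of 10513 were higher and 2488 lower (57.6% in all). Counts of called members in the lists and families below are to be read against these shares. The labels do not say whether the 3 endosperm samples came from separate plants, so p-values measure only the spread between these samples, and the test against 1 reference RNA leaves out the spread of the reference itself.

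Among probes with a gene name, AT3G15960 had the highest ratio, with a log2 ratio of 3.58 ± 0.04 (SD, n = 3), or 12.0-fold (limma adjusted p = 0.000125). AT5G05030 (3.45 ± 0.39) and AT2G20170 (3.34 ± 0.80) came next. AT1G59920, AT5G63250, AT2G04750, AT4G26470, AT3G25280, AT5G41250 and AT5G07160 followed, with AT1G59920 highest of these at 3.23 ± 0.34. Of these 10, AT3G25280 encodes the transporter NPF4.2 of the nitrate and peptide transporter family. The lowest ratio was that of AT3G15650, at -5.03 ± 0.67, or 32.6-fold below the reference (adjusted p = 0.00013). GH3.3, which encodes an enzyme that conjugates auxin to amino acids, was at -4.90 ± 0.61, and AT5G42530 was at -4.85 ± 0.30. SWEET11, which encodes a plasma membrane sucrose transporter, was at -4.84 ± 0.86 (28.7-fold lower, adjusted p = 0.000176). The others of the lowest 10 were AT2G25510, AT2G30540, AT1G67860, AT1G64370, AT1G67750 and ATPMEPCRD, between -4.71 and -4.45. The replicates of AT1G67750 were the furthest apart of these 20 genes, from -5.62 in replicate 1 to -2.97 in replicate 3.

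**Figure D1:**
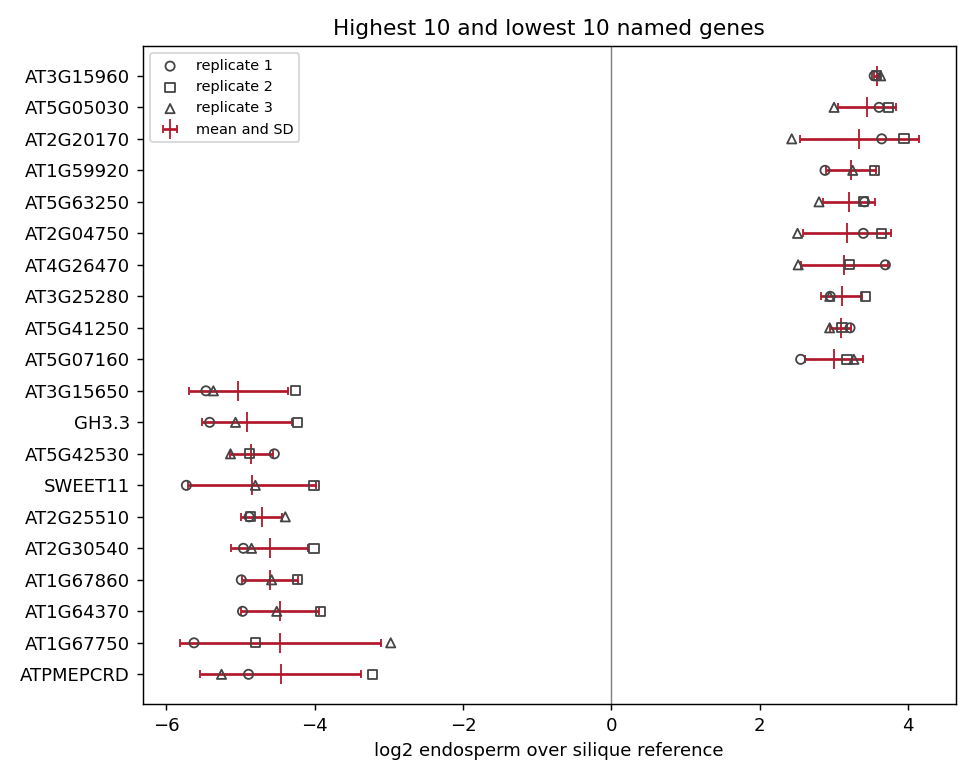
Log2 ratio of endosperm over silique reference (horizontal axis) of the 10 highest and 10 lowest named genes, 1 per row. Open symbols are the 3 replicates and the red marks their mean and SD; the highest mean is 3.58 (AT3G15960) and the lowest means lie between -5.03 and -4.45.

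Markers of the tissues that a sample could hold were compared next. Of the 11 measured endosperm markers 10 were higher, with a median log2 ratio of 1.72, and the same number passed when adjusted over the list alone. The count was 9 without replicate 1, without replicate 3 and with each array centred on its median. It was 8 without replicate 2 and on the Cy5 arrays alone, and 6 against a fold change of 1.5. The type I MADS-box genes PHE2 and AGL35 were at 2.97 ± 0.05 and 2.94 ± 0.05 (7.81-fold and 7.69-fold, both adjusted p = 0.000157). PHE1, a paternally expressed imprinted gene, was at 2.33 ± 0.45, AGL40 at 1.97 ± 0.25 and AGL62, which holds back endosperm cellularisation, at 1.72 ± 0.44. IKU1 was the marker that did not pass, at 0.10 ± 0.25. PHE1 and PHE2 are close relatives, and how far a probe of one takes up transcript of the other was not measured. Since this list set the direction of the ratios, its sign is no evidence of its own. Its camera adjusted p was 0.00126 with a preset correlation between genes, and the call was lost with an estimated correlation (adjusted p = 0.624 with an estimated correlation).

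ALC, a regulator of the fruit's opening zone and the 1 measured gene of the silique wall and vascular list, was 5.29-fold lower in endosperm (log2 ratio -2.40 ± 0.22, adjusted p = 0.000194). Of 3 measured seed coat markers 1 was lower, over all genes and adjusted over the list alone: INO, a regulator of the outer integument, at -0.73 ± 0.27 (adjusted p = 0.00794). BAN and DFR, enzymes of the flavonoid pathway, did not pass, at -0.39 ± 0.28 and 0.15 ± 0.27. As a list the seed coat markers did not pass against other genes (camera adjusted p = 0.372). Without replicate 1, and with each array centred on its median, 2 of the 3 markers were lower in place of 1, since BAN passed (adjusted p = 0.0224 and 0.0328). BAN also passed on the Cy5 arrays alone (-0.55, adjusted p = 0.0263), with the dye as a covariate (adjusted p = 0.0234) and with the arrays of replicate 2 kept apart (adjusted p = 0.0226 as 4 samples and 0.0331 as a random block). INO was at -1.05 and -1.03 on the Cy3 arrays and at -0.17 and -0.55 on the Cy5 arrays, and did not pass on the Cy5 arrays alone (-0.36, adjusted p = 0.111). No embryo marker and no gene of the seed storage and oil body list was measured on all 4 arrays (0 of 19 and 0 of 10).

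Genes of photosynthesis lay close to the reference. Of 11 measured genes, 1 was higher, 3 were lower and 7 did not pass, with a median log2 ratio of -0.13. That median was -0.05 without replicate 1, -0.08 without replicate 2, -0.22 with each array centred on its median and 0.01 on the Cy5 arrays alone. Adjusted over the list alone, 0 were higher and 2 lower. RCA, which encodes Rubisco activase, was at -1.34 ± 0.66 (2.53-fold lower), and the light-harvesting genes LHCB4.2 and LHCB1.5 were at -0.64 ± 0.09 and -0.69 ± 0.57. PRK, which encodes phosphoribulokinase of the Calvin cycle, was higher, at 0.55 ± 0.31 (1.46-fold). The photosynthesis list did not pass against other genes (camera adjusted p = 0.372). PRK did not pass without replicate 2 (adjusted p = 0.103), without replicate 3 (adjusted p = 0.128), on the Cy3 arrays alone (adjusted p = 0.09) or with each array centred on its median (adjusted p = 0.0565). The call of LHCB1.5 was lost without replicate 2 (adjusted p = 0.0602) and without replicate 3 (-0.37, adjusted p = 0.14), and on the Cy3 arrays alone it was at -0.10 (adjusted p = 0.661). It was also lost with the arrays of replicate 2 kept apart (adjusted p = 0.0537 as 4 samples and 0.0789 as a random block). RCA did not pass on the Cy5 arrays alone (-0.91, adjusted p = 0.0505).

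Genes of cell division were represented by few probes with a gene name. All 4 measured genes of DNA replication were higher, also adjusted over the list alone. ICU2, the catalytic subunit of DNA polymerase alpha, was at 1.31 ± 0.23 (2.48-fold), FEN1, a flap endonuclease, at 1.24 ± 0.43, CDC6B at 1.07 ± 0.80 and MCM7, a subunit of the replicative helicase, at 0.69 ± 0.35. All 3 measured genes of spindle and cytokinesis were higher, also adjusted over the list alone. The phragmoplast kinesins PAKRP2 and PAKRP1L were at 1.84 ± 0.54 (3.57-fold) and 1.55 ± 0.35 (2.92-fold), and KEU, which acts in membrane fusion at the cell plate, was at 0.51 ± 0.20. Of 3 measured cell cycle genes, the aurora kinases AUR3 (1.93 ± 0.30) and AUR1 (0.92 ± 0.12) were higher and AUR2 did not pass (0.36 ± 0.62), and 2 passed when adjusted over the list alone. Against all other genes these lists did not pass (camera adjusted p = 0.142 for replication, 0.142 for spindle and cytokinesis and 0.186 for the cell cycle). The test fry asks whether a list moves 1 way on average, without other genes as a comparison. By fry these lists passed (adjusted p = 0.0185, 0.0457 and 0.0363), as did all other tested lists except photosynthesis (0.257) and cytokinin (0.15). With 57.6% of all genes called, that is a looser question. A pass by fry also does not need most genes of a list to move 1 way. The tubulins passed downwards (fry adjusted p = 0.0478) with a median log2 ratio of 0.05. Core histones passed upwards (fry adjusted p = 0.0478) with genes called in both directions. CDC6B did not pass without replicate 1 (adjusted p = 0.0511) or on the Cy5 arrays alone (adjusted p = 0.0923). MCM7 did not pass without replicate 2 (adjusted p = 0.0687) or without replicate 3 (adjusted p = 0.0655), and KEU did not pass without replicate 2 (adjusted p = 0.0596) or without replicate 3 (adjusted p = 0.0512), nor on the Cy5 arrays alone (adjusted p = 0.0746).

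Core histone genes moved in both directions. Of 18 measured genes 6 were higher, 1 was lower and 11 did not pass, and the counts were the same when adjusted over the list alone (6 higher and 1 lower). Over all 10513 measured genes 3571 were higher, a share close to that of the histones, and 2488 were lower. The number higher was 4 without replicate 2 and without replicate 3, 7 without replicate 1 and 8 with the dye as a covariate, each with 1 lower. HTR12, the centromeric histone H3, was highest at 1.61 ± 0.16 (3.04-fold). HTB1, a histone H2B gene, was at 1.16 ± 0.29 and the histone H3 gene HTR3 at 1.05 ± 0.12. A histone H4 gene (AT3G53730) was at 0.84 ± 0.12, while the other measured H4 genes did not pass and lay between -0.34 and 0.15. HTR5, which encodes the replacement variant H3.3, was lower, at -1.14 ± 0.37 (adjusted p = 0.00268). The other measured genes for H3.3 did not pass and lay between -0.01 and 0.15, so the lower level does not hold for H3.3 genes in general. The core histone list did not pass against other genes (camera adjusted p = 0.347). Of 5 measured tubulin genes 1 was lower, TUB5, at -3.57 ± 0.18 (11.9-fold lower, adjusted p = 0.000157), also adjusted over the list alone. TUA1, TUA2, TUA5 and TUB9 did not pass and lay between 0.03 and 0.56. Because of TUB5 the median of the list (0.05) and its mean (-0.57) differ in sign, and its test ran downwards without passing (camera adjusted p = 0.541). With each array centred on its median the list's median was -0.05. TUA2 passed as higher without replicate 1 (0.92, adjusted p = 0.0187), with the dye as a covariate (adjusted p = 0.00642) and on the Cy5 arrays alone (adjusted p = 0.00329), whereas on the Cy3 arrays alone it was at -0.09. SIM, a CDK inhibitor, did not pass (-0.30 ± 0.29).

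**Figure D2:**
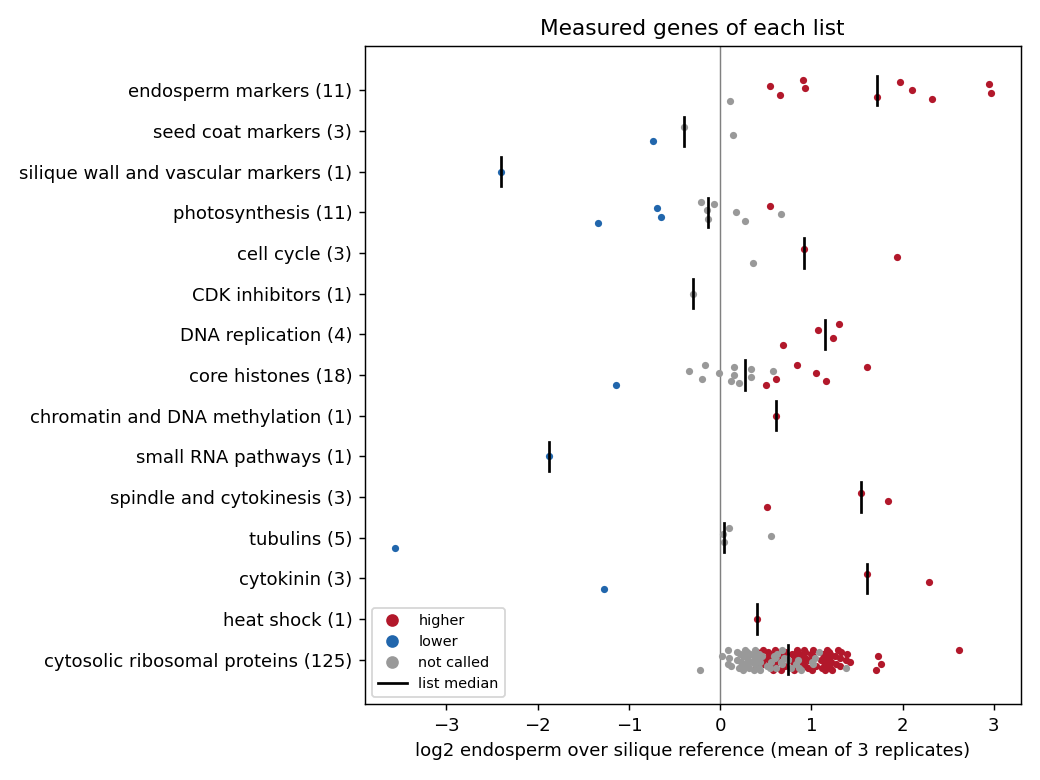
Log2 ratio of endosperm over silique reference (horizontal axis, mean of 3 replicates) for the measured genes of each list, with the number of genes in brackets. Points are genes, red where higher, blue where lower and grey where not past the threshold, and the black bar is the list's median; 10 of 11 endosperm markers and 70 of 125 ribosomal protein genes are red.

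Of 3 measured cytokinin genes 2 were higher and 1 was lower, over all genes and adjusted over the list alone. RR21 and RR19, type-B response regulators that act as transcription factors, were at 2.28 ± 0.32 (4.87-fold) and 1.61 ± 0.99 (3.05-fold). RR15, a type-A response regulator, was at -1.27 ± 0.17 (2.41-fold lower, adjusted p = 0.000699). The list as a whole did not pass against other genes (camera adjusted p = 0.654). Other lists had 1 measured gene each. DME, a DNA glycosylase that removes methylated cytosine, was higher at 0.62 ± 0.45, and AGO7, the argonaute of trans-acting small RNAs from TAS3, was 3.67-fold lower (-1.88 ± 0.40, adjusted p = 0.000577). HSP17.6C, a small heat shock protein gene, was at 0.40 ± 0.18 (adjusted p = 0.0411). DME did not pass without replicate 1 (adjusted p = 0.058) or without replicate 2 (adjusted p = 0.0503), and HSP17.6C did not pass without replicate 2 (adjusted p = 0.161) or without replicate 3 (adjusted p = 0.203). Centring each array on its median also ended both calls (adjusted p = 0.0554 for DME and 0.0983 for HSP17.6C), as did the Cy5 arrays alone for DME (adjusted p = 0.0858) and the Cy3 arrays alone for HSP17.6C (adjusted p = 0.211).

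Genes of cytosolic ribosomal proteins, listed by locus after the data were examined, were higher as a group. Of 125 measured genes 70 were higher, 0 were lower and 55 did not pass, with a median log2 ratio of 0.75, and the counts were the same when adjusted over the list alone (70 higher and 0 lower). The number higher was 56 on the Cy3 arrays alone, without replicate 2 and without replicate 3, and 90 without replicate 1. It was 104 on the Cy5 arrays alone and 103 with the dye as a covariate. AT5G09490 was at 2.62 ± 0.16 (6.16-fold), AT4G29410 at 1.73 ± 0.15, AT3G06680 at 1.42 ± 0.20 and AT2G44120 at 1.33 ± 0.04. The camera adjusted p was 2.58e-08, and the call was lost with an estimated correlation (adjusted p = 0.624 with an estimated correlation). The size of the shift went with the dye: the medians were 0.35 (replicate 1, Cy3), 0.33 (replicate 2, Cy3), 0.88 (replicate 2, Cy5) and 1.09 (replicate 3, Cy5). Between the 2 arrays of replicate 2, 96 of the 125 genes had the higher ratio where endosperm carried Cy5. Against a fold change of 1.5, 30 of the 125 genes passed.

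**Figure D3:**
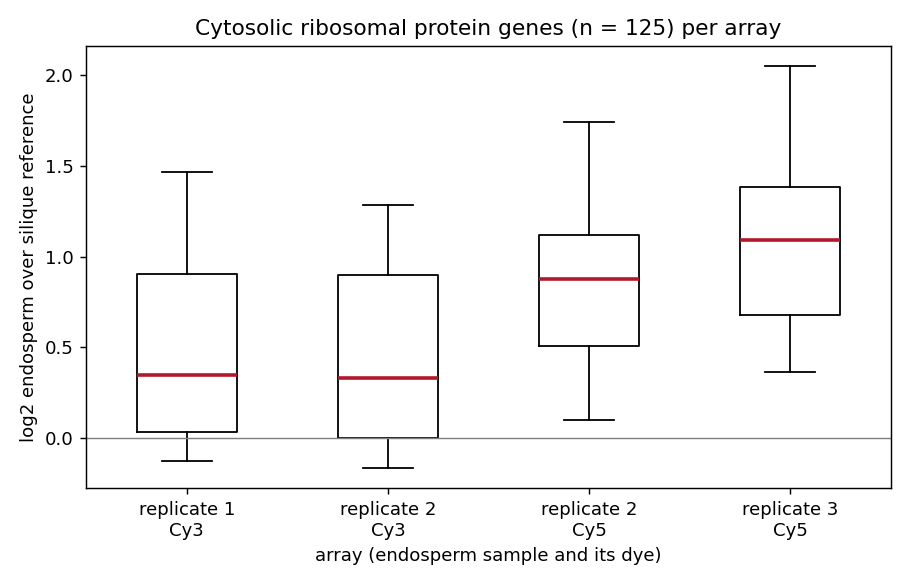
Log2 ratio of endosperm over silique reference (vertical axis) of 125 cytosolic ribosomal protein genes on each of the 4 arrays (horizontal axis). Boxes span the quartiles, whiskers the percentiles 5 to 95 and red lines the medians, which are 0.35 and 0.33 with Cy3-labelled endosperm and 0.88 and 1.09 with Cy5-labelled endosperm.

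The effect of the dye was tested on the 4 arrays with a dye term. With the arrays taken as independent no probe passed (0 of 19449, limma), and 1828 probes (9.40%) had an unadjusted p under 0.05. With the arrays of replicate 2 as a random block, at a correlation of 0.33 estimated by moments, 14 probes passed and 2235 (11.5%) had an unadjusted p under 0.05. Replicates as fixed blocks would leave 0 residual degrees of freedom. The ribosomal protein genes had a median difference of 0.28 between the Cy5 and the Cy3 array of replicate 2, the core histone genes 0.29 and the endosperm markers -0.02. Seed coat markers had 0.33, while replication genes (-0.20) and spindle and cytokinesis genes (-0.19) went the other way. None of the 4 replication genes was higher with Cy5. The remaining tested lists lay between 0.01 (cytokinin) and 0.11 (photosynthesis). Between replicates 1 and 3 the dye and the sample cannot be told apart, so the term rests on replicate 2 for the part that is dye alone.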

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

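Arrays of 1 dye orientation, the count without the genes with 17 probes, the moment estimate of a block correlation and the ribosomal protein list were chosen after the data were examined. The count of 11188 probes stayed within 1.5 times under all settings except a fold threshold of 1.5 (4885 probes) and gene-level means (6059 genes, since fewer items were tested). Leaving out each replicate gave 8490 to 11012. With the dye as a covariate 12546 probes passed, which included 99.99% of the probes called without it; the balanced dyes leave the ratios themselves as they are. Centring each array on its median gave 10967, of which 49.4% were higher against 55.7% for the values as deposited (50.6% and 44.3% if the ratio ran the other way). The standard estimate of the correlation within replicate 2 gave no value for 4 arrays, and a moment estimate (0.33) gave 11713. The dye term called 0 probes under each setting fixed beforehand and 14 with replicate 2 as a random block, chosen after the data were examined. The endosperm marker and ribosomal protein lists lost their calls with an estimated correlation (camera adjusted p = 0.624 for each) and passed under the other list settings tried. With an estimated correlation camera uses the 2 residual degrees of freedom. The replication list was also at 0.624 there, with an estimated correlation of -0.226. The equal values come from the adjustment over lists: unadjusted camera p was 0.158 for endosperm markers and 0.32 for ribosomal protein genes. Their estimated correlations were 0.203 and 0.367, above the preset 0.01 on which their calls rest. Whether few degrees of freedom or correlation between genes ended these calls cannot be told apart. A call lost in that form does not tell a weak list from a strong one, and the preset form leaves out correlation above 0.01. Tubulins, not past the threshold by camera in any setting, turned upwards on the Cy5 arrays alone (camera adjusted p = 0.984). The cause was not tested. The rule for named genes took genes with 1 sign on all 4 arrays or, from most lists, those with the smallest p. Most genes named outside it were chosen because they had not passed. How often signs changed in these groups is therefore no check of stability. Of the 56 genes named by the rule none changed sign. Of the 9 named outside it, 6 did, never past the threshold: DFR (-0.011 without replicate 3, -0.094 with Cy3 alone, 0.234 without replicate 1), AUR2 (-0.0014 without replicate 1, -0.034 with Cy5 alone, 0.543 without replicate 3), TUA2 (-0.088 with Cy3 alone), TUA5 (-0.079 without replicate 3, 0.235 without replicate 1), TUA1 (-0.046 centred and without replicate 2, 0.112 without replicate 1) and TUB9 (-0.062 centred, -0.047 with Cy3 alone, -0.041 without replicate 3, -0.040 without replicate 2, 0.167 without replicate 1). Among the 56, the fold threshold ended 13 calls, and leaving out replicates 1, 2 and 3 ended 2, 6 and 5, with fewer samples. The Cy3 arrays alone ended 3 and the Cy5 arrays alone 5. No paired analysis was possible because there is 1 group and the reference is 1 RNA. Spot brightness over background is not in the values used, so what it limits is not known.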

Other observations

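All tests in this part except the turning of replicate signs were chosen after the values they rest on, or part of them, had been seen, and genes are named here after their values were seen. Gene families, taken as symbol stems shared by at least 5 measured genes (37 families), were compared with all other genes after low SWEET genes had been noticed and a first pass had held stems of clone names and duplicate families, since dropped. Of 14 measured SWEET genes, a family of sugar transporters, 9 were lower and 2 higher, with a median log2 ratio of -1.99. SWEET11 (-4.84 ± 0.86), SWEET10 (-4.16 ± 0.23), SWEET4 (-3.74 ± 0.70) and SWEET13 (-3.74 ± 0.56) were among the lowest, SWEET14 lay between -4.76 and -2.77 in the 3 replicates, and SWEET8 (1.21 ± 0.40) and SAG29, also known as SWEET15 (0.92 ± 0.12), were higher. This was the 1 family of 37 that passed (camera adjusted p = 0.0179, and adjusted p = 0.693 with an estimated correlation, with which no family passed). Its median was negative under each scaling tried and with either dye, between -2.14 and -1.70.

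No other family passed, and those given next were picked after their values were seen. Of 10 measured alpha-expansins 7 were lower and 1 was higher (camera adjusted p = 0.0882), with EXPA8 at -3.44 ± 0.34 and EXPA7 at 1.44 ± 0.34. Of 20 TBL genes 11 were lower and 5 higher (adjusted p = 0.195), with TBL38 at -3.34 ± 0.64 and TBL42 at 1.89 ± 0.26. Of 13 genes with the stem GH, which joins GH9 glycosyl hydrolases with GH3.3, 8 were lower and 3 higher (adjusted p = 0.195), with GH9B5 at -2.60 ± 0.37 and GH9C1 at 2.33 ± 0.75. Of 6 XTH genes, which act on xyloglucan of the cell wall, 1 was lower and 1 higher (adjusted p = 0.565). Of 13 photosynthesis genes found by name 3 were higher and 2 lower, and 5 of the 13 were already in the fixed list. PORB, an enzyme of chlorophyll synthesis (2.49 ± 0.11), TROL (0.83 ± 0.38) and HCF101 (0.58 ± 0.35) were higher. LHCB4.2 (-0.64 ± 0.09) and LHCB1.5 (-0.69 ± 0.57), both shared with the fixed list, were lower. The 13 genes together had a median of -0.13 (limma's camera, adjusted p = 0.687 for this 1 list). The shared gene PSBW sets the median of each list, so the equal medians are not separate evidence. RR18, another type-B response regulator, lacked a value on the Cy3 array of replicate 2 and lay between 1.09 and 1.29 on the others. Genes next to each other on a chromosome had slightly similar ratios (r = 0.09 across 4016 pairs, permutation adjusted p = 0.006 over 6 distances, from the smallest p that 1000 shuffles can give). At 2 and 3 genes apart r was 0.04 (adjusted p = 0.032) and 0.05 (adjusted p = 0.027), and at 5 genes apart it was -0.01 (adjusted p = 0.62). Neighbouring copies of 1 gene were not left out of the pairs. How far their probes take up each other's transcript was not measured, so an effect of position cannot be told apart from this.

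The low SWEET genes were found and tested on the same data, so their low level as a family remains a hypothesis. If 1 abundant member had set the signal at every SWEET probe, the members would share a ratio. Their SD between members was 4.87 times their mean SD between replicates, which argues against that. Among the 6 members under -3 the same ratio was 0.99, so cross-hybridisation among these cannot be told apart from a shared level, since they were picked for being low. A difference between endosperm and the other silique tissues stays open and was not tested further.

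Photosynthesis genes lay near a ratio of 1, although the reference holds the green silique wall. For carry-over of wall tissue, under 1% of probes called over 4-fold below the reference was predicted. The share was 5.34% (1.75% if the ratio ran the other way, also above that 1%). Transcripts of other tissues in the reference could lie that low even with wall carried over. The share therefore shows only that the captured samples were unlike the reference, and carry-over of wall cannot be told apart. Carry-over of seed coat cannot be told apart, since 3 markers were measured, with a median of -0.39. Spots clamped at saturation cannot be told apart either: the SD between replicates of the list was 1.505 times that of other genes near a ratio of 1, with a 95% bootstrap interval from 0.618 to 2.74, and no intensities were used. A tissue difference in either direction also stays open, untested.

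The 2 arrays of replicate 2, which hold the same RNAs, differed by an SD of 0.42, about as much as arrays of different samples with the same dye (0.47 and 0.44). The difference between them went with that between replicates 3 and 1, which share no array with it (r = 0.347 across probes, 95% bootstrap interval over probes 0.324 to 0.371), so a dye bias that recurs by probe may account for part of it. That interval treats probes as independent and leaves out the spread between arrays and samples. Separate processing of the 2 orientations cannot be told apart from a dye bias, because no other sample was labelled both ways. Of the called probes 99.99% kept call and sign with the dye as a covariate, but that share decides nothing, because the balanced dyes fix the mean ratios in that fit: by design a dye bias equal on all arrays cancels in the mean and cannot set these ratios, while one that differs between arrays was not tested. With the sign of 1 replicate turned, the highest number of calls was 0 against 11188, but 4 sign patterns, of which 1 gave as many, are too few for a share under 0.05.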
